A study of Mus musculus with 8 samples.

How the data were processed

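Lineage-negative bone marrow cells were prepared from 4 Rnaseh2b knockout mice and 4 littermate controls, and GMP were sorted by flow cytometry as lineage-negative, Kit-expressing cells with high CD16/32 and CD34, per the labels' protocols. Polyadenylated RNA was made into strand-specific libraries and sequenced as paired ends, per the labels' protocols. The submitters' processing notes name FastQC, GSNAP 2020-12-16, featureCounts 2.0.1, DESeq2 1.30.1, R 3.5.1 and the build mm10. The annotation release and the strand setting of the counting are not given in the sources used here.

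The deposited table holds 1 signal value per gene and library for 23131 genes: gene counts that the authors divided by 1 factor per library and rounded to 1 decimal. The values are whole multiples of a step that differs between libraries. Within a tolerance of 0.051 normalised counts, 99.9988% of the values above 0 came out as whole reads and 2 did not. The reads recovered in this way gave the depth of each library, 28352720 to 45655518 reads. Of the identifiers, 23108 were found in GENCODE M21, 22956 of them with the same start and end, and 8 symbols are shared by 2 identifiers, of which the one with the higher mean was used. Pseudogenes took 12.2 ± 0.60% of the values in controls and 12.0 ± 0.64% in knockouts (SD, n = 4 each).

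Groups were taken from the labels, which name separate mice, so p-values reflect the spread between mice. Replicate numbers are not shared between the groups and pair no mice. Pairs of libraries of 1 group differed by 14.0 to 45.6 times the sampling noise (chi-square per degree of freedom over genes), so no library was counted as a copy of another.

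The main test was limma 3.58.1 in R 4.3.3 on log2(normalised count + 1), with an intensity trend, for the 16688 genes with a mean of at least 10, and Benjamini-Hochberg adjusted p below 0.05. Fold changes are on that scale, which understates the change of low genes. Values are normalised counts, as mean ± SD over 4 libraries per group unless stated. Intervals and read totals cover counting error only, since reads amplified by PCR are not independent molecules. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 32 lists, and beside it with an estimated correlation and with fry. fry, which asks whether a list's genes move one way on balance, called 5 lists: p53 target genes, interferon-stimulated genes, stem cell and multipotent progenitor genes, senescence and cell cycle inhibitors, and stromal and endothelial genes. Each list was also counted over all genes tested and adjusted over the list alone. In the later neutrophil, monocyte and macrophage, dendritic cell, megakaryocyte, nucleic acid sensor, and unfolded protein and integrated stress response lists the median, the mean and the camera direction did not all agree in sign, so their tests are reported without a conclusion on the direction of the list.

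Genes to be named were chosen by a rule set before the data were examined, as were the lists and the main alternatives. Among genes past the threshold with a mean of at least 50, a symbol that is no predicted-gene or clone name and groups that do not overlap, the rule takes the 12 largest rises and the 12 largest falls. It adds Rnaseh2a, Rnaseh2b, Rnaseh2c, Trp53 and the sex-linked genes, and for each list described up to 5 members past the threshold with the lowest adjusted p or, with none, the 2 with the highest mean. Lists with neither a gene nor a list call are given by their test only. A gene named outside the rule is marked where it appears, and 1 gene that the rule takes is not reported here. The 4 knockouts and the 4 controls did not overlap for 1237 genes (7.41% of those tested, where chance gives 2.86%), and 230 of the 234 changed genes were among them.

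On simulated counts for the comparison of knockout with control (16605 genes tested), limma recovered 59.7% of 67 genes changed 1.5-fold, 77.6% of 67 changed 2-fold and 89.4% of 66 changed 4-fold. Of its 159 calls 5.03% were false, and with no simulated change it made 0 calls over 16588 genes. edgeR 4.0.16 made 165 calls, 7.27% false, and DESeq2 1.42.0 made 184, 13.0% false. The simulation drew each gene independently and held no structure between libraries, so these rates need not hold for the real data. On the recovered reads the quasi-likelihood test of edgeR called 241 genes (228 shared with limma) and DESeq2 called 558 (234 shared; its adjusted p was missing for 28). Other alternatives were pseudocounts of 0.5 and 5, no filter, a mean of at least 50, equal totals, quantile normalisation, no trend, array weights, a minimum 2-fold change and each library left out. Chosen after seeing the data were leaving out control 1 and knockout 8 together, testing protein-coding genes alone, the score of the immediate early or later neutrophil list as a covariate, and the estimated correlation without knockout 8. The count of genes was also made for each of the 35 splits of the 8 libraries into 4 and 4. Figures were drawn with matplotlib 3.10.9.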

Results

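Granulocyte-macrophage progenitors (GMP), the bone marrow cells that give rise to neutrophils and monocytes, were profiled by RNA sequencing in C57BL/6 mice. The 8 libraries came from 4 mice in which Vav-Cre, a recombinase active in blood-forming cells, acts on floxed Rnaseh2b, and from 4 Cre-negative littermates with the same floxed alleles. They are called knockout replicates 5 to 8 and control replicates 1 to 4. Rnaseh2b encodes a subunit of RNase H2, the enzyme that removes ribonucleotides from genomic DNA and cleaves RNA in RNA-DNA hybrids. The comparison asked which transcripts differ in GMP when Rnaseh2b is deleted. Reads assigned to genes were 45655518, 37580789, 28352720 and 39165032 in controls 1 to 4 and 38917550, 35557641, 34976865 and 36757466 in knockouts 5 to 8. The first principal component held 26.0% of the variance and separated the groups. The second held 17.7% and set knockout 8 (-49.7) and control 1 (34.6) apart from the other libraries, which lay between -13.96 and 10.95.

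Rnaseh2b (ENSMUSG00000021932), on chromosome 14 from 62292589 to 62372992 (mm10), was the check of the genotype. Its normalised count was 2288, 2470, 1249 and 1207 in controls 1 to 4, and 117.9, 127.5, 75.9 and 95.3 in knockouts 5 to 8. The knockouts kept 5.78 ± 1.29% of the control mean (SD, n = 4), a log2 fold change of -4.05 ± 0.236 (SE; limma adjusted p = 3.76e-07). No library went against its label, and the highest control stood at 2.05 times the lowest. Gene totals do not separate reads on exons outside the deleted part from reads of cells that kept the gene. The partner subunits did not pass the test: Rnaseh2a had 2243 ± 93.3 in controls and 2122 ± 160 in knockouts, and Rnaseh2c had 3025 ± 257 and 3034 ± 106 (SD, n = 4 each). Both overlap another expressed gene on the opposite strand (Prdx2 and Kat5), and the strand setting of the counting is not given in the sources used here. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were expressed in both groups, at 2400 ± 227, 2059 ± 199, 1092 ± 47.4 and 895 ± 155 in controls and 2344 ± 171, 1691 ± 491, 960 ± 78.6 and 838 ± 41.1 in knockouts.

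**Figure D1:**
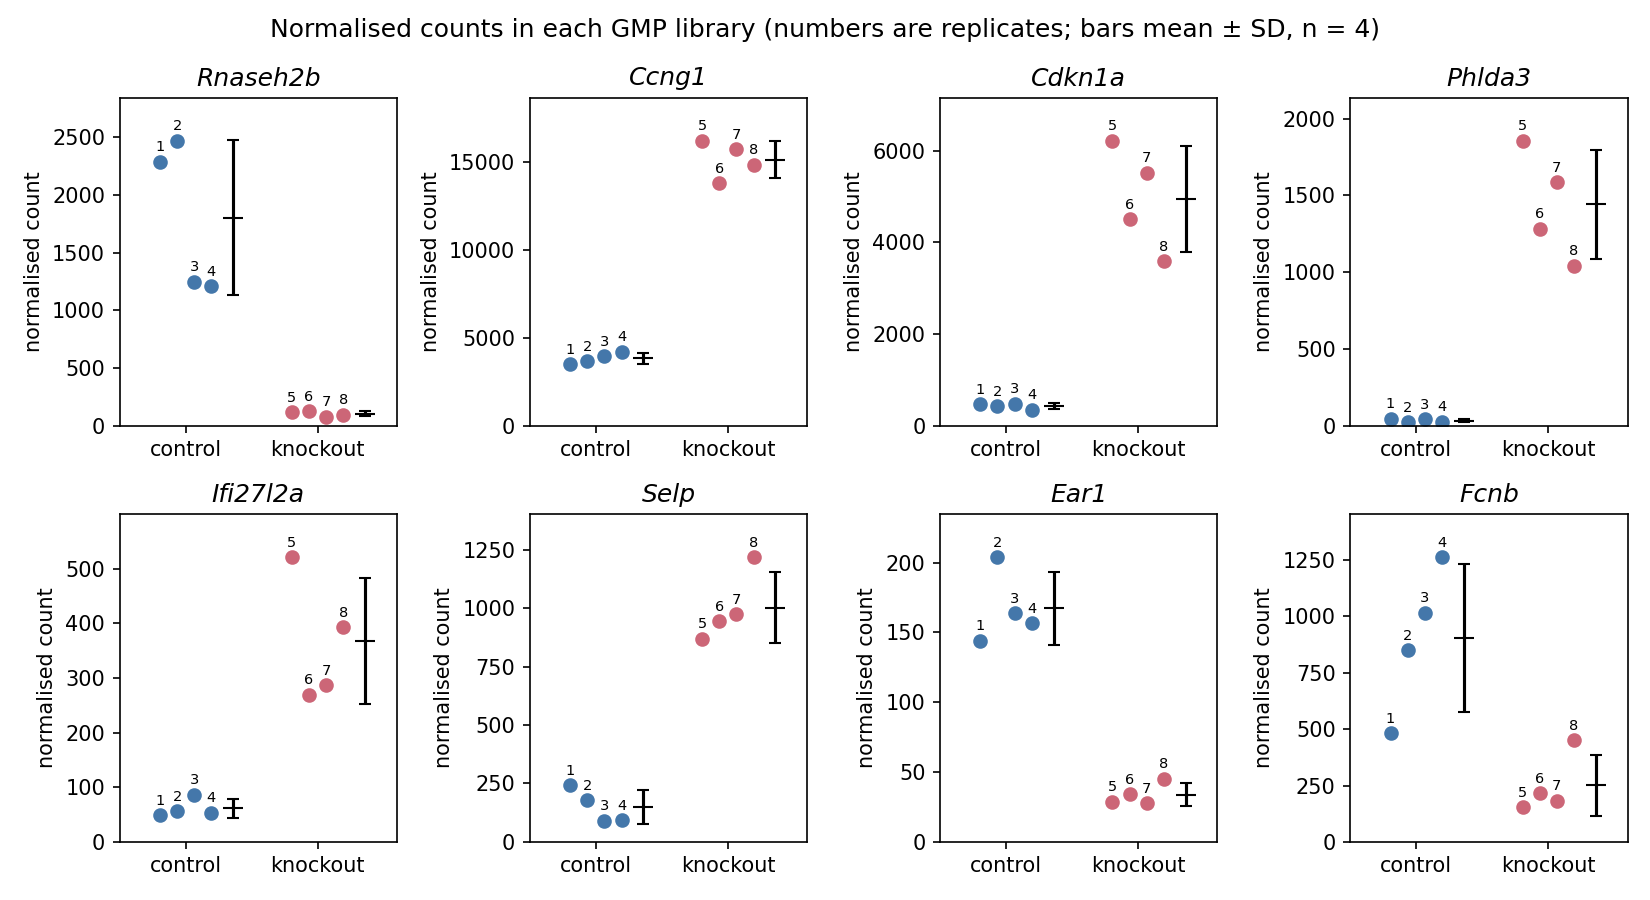
Normalised count (vertical axes, from 0) of 8 genes in each library, with the replicate number above each point and black bars for the group mean ± SD (n = 4). Rnaseh2b lies between 75.9 and 127.5 in knockouts and between 1207 and 2470 in controls, and no gene shown has overlapping groups.

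Loss of Rnaseh2b was accompanied mainly by rises. Of 16688 genes tested, 234 changed (limma, Benjamini-Hochberg), 199 upward and 35 downward. The lowest adjusted p belonged to Ccng1 (ENSMUSG00000020326), which encodes cyclin G1 and lies on chromosome 11 from 40748552 to 40755311. Ccng1 rose 3.96-fold, from 3820 ± 315 to 15128 ± 1071 (SD, n = 4 each; adjusted p = 7.61e-09). Cdkn1a (ENSMUSG00000023067), the gene of the cell cycle inhibitor p21, lies on chromosome 17 from 29090976 to 29100727 and rose 11.4-fold, from 427 ± 60.7 to 4955 ± 1154 (adjusted p = 1.48e-08).

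By the naming rule, the 12 largest rises were Eda2r, Tnfsf4, Zfp365, Epha2, Inka2, Phlda3, Trp53cor1, Hmcn2, Zmat3, Sulf2, Cdkn1a and Bbc3, with log2 fold changes from 3.13 to 7.59 and, as that rule requires, all 4 knockouts above all 4 controls. Phlda3 went from 33.5 ± 11.8 to 1442 ± 355, Zmat3 from 67.0 ± 35.3 to 1251 ± 226, Sulf2 from 153 ± 63.3 to 1797 ± 389 and Bbc3 from 122 ± 31.1 to 1078 ± 281. Trp53cor1, a long non-coding RNA next to Cdkn1a, went from 3.8 ± 2.6 to 147 ± 40.2. Several of these genes were near 0 in controls, so that their fitted folds depend on the pseudocount. Eda2r, a receptor of the TNF receptor family, had 6 reads in the controls together and 1309 in the knockouts, and Tnfsf4, the OX40 ligand, had 6 and 980. Zfp365 had 2 reads in controls and 762 in knockouts, a ratio of 383 at equal depth with a 95% counting interval from 106 to 3169. Epha2 had 16 and 2060 reads, and Inka2 12 and 1241. The fitted log2 fold change moved by over 1.5 times on the linear scale for Eda2r (8.22) and Tnfsf4 (7.85) without control 1, for Epha2 (6.22) and Inka2 (7.55) without control 2, and for Trp53cor1 (4.57) without control 1. Sulf2 overlaps Ncoa3 on the opposite strand, so its level is uncertain.

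The 12 largest falls were Rnaseh2b, Gzmb, Ear2, Ear1, Fcnb, Tspan9, Nrg1, St8sia6, Ncam1, Acp1, Sdc2 and Olr1, with log2 fold changes from -4.05 to -0.94 and, as the naming rule requires, all 4 knockouts below all 4 controls. Gzmb, which encodes granzyme B, went from 187 ± 24.6 to 33.9 ± 17.8, and Fcnb, which encodes ficolin B, from 903 ± 328 to 251 ± 136. Nrg1, the neuregulin 1 gene, went from 825 ± 71.8 to 316 ± 66.9, Ncam1 from 1249 ± 341 to 592 ± 138 and Acp1 from 1419 ± 94.7 to 742 ± 129. Leaving out 1 library ended the calls of Ear2 (adjusted p 0.0652 to 0.1501 without any 1 control or knockout 5), Tspan9 (0.0530 and 0.0520 without control 2 or 4) and St8sia6 (0.0717 to 0.0975 without control 2, 3 or 4 or knockout 5, 6 or 7). It also ended those of Sdc2 (0.0689 to 0.146 without control 2, 3 or 4 or knockout 5 or 7) and Olr1 (0.0573 to 0.0803 without control 3 or 4 or knockout 5 or 7), and the log2 fold change of Ear2 was -1.70 without knockout 7. With no intensity trend the calls of Ear2, Fcnb, Tspan9, St8sia6, Ncam1 and Olr1 were lost (0.105 to 0.241).

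The balance of rises and falls depended on single libraries. Without knockout 8, 569 genes changed (342 higher, 227 lower), and without control 1, 371 did (268 higher, 103 lower). Leaving out knockout 7, control 4 or knockout 6 gave 135, 139 and 152 genes. With control 1 and knockout 8 left out together, a choice made after seeing the data, 1440 genes changed (651 higher, 789 lower), 231 of them among the 234. With both left out, all knockouts come before all controls in the sample numbers of the labels, so genotype and sample order cannot be told apart. Without knockout 8 alone, all knockouts also come first.

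**Figure D2:**
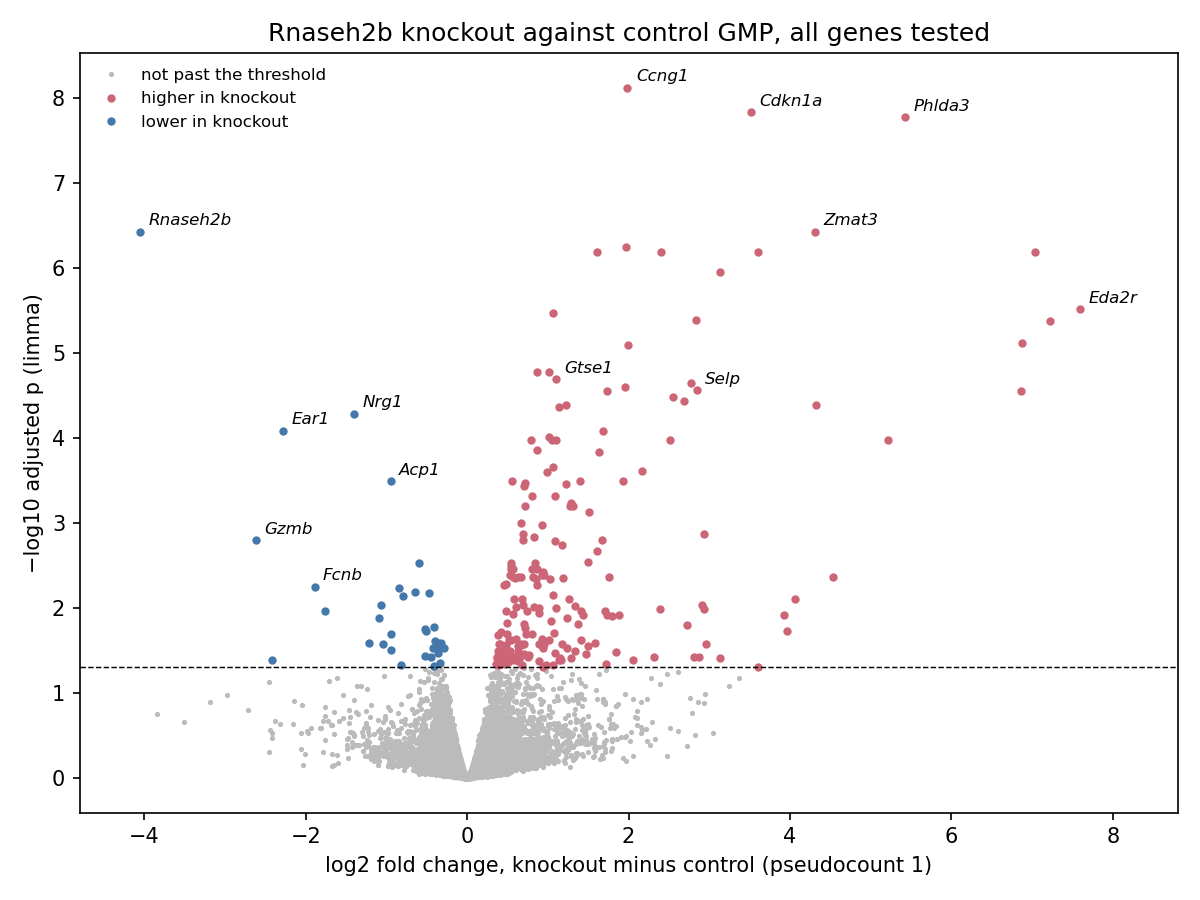
Each point is 1 of 16688 genes tested, with the log2 fold change of knockout over control (horizontal axis) against −log10 of the limma adjusted p (vertical axis); the dashed line is the threshold of 0.05. The 199 genes that were higher in knockout lie to the right and the 35 that were lower to the left, with Ccng1, Cdkn1a and Phlda3 at the top.

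Genes induced by the transcription factor p53 rose together. Of 39 tested members of that list, 25 rose and none fell over all genes tested, and 28 rose adjusted over the list alone. The 5 with the lowest adjusted p were Ccng1, Cdkn1a, Phlda3, Zmat3 and Pmaip1. Pmaip1 and Bbc3 encode the pro-apoptotic proteins NOXA and PUMA, and Pmaip1 went from 252 ± 27.2 to 985 ± 99.2, a 3.91-fold rise (adjusted p = 5.71e-07). The list's median fold was 2.10 (camera adjusted p = 5.31e-54), and it was the one list of the 32 tested whose call held with an estimated correlation (adjusted p = 0.00912 with an estimated correlation). The list score, the mean log2 difference from the control mean, was 1.59 to 2.00 in the knockouts and -0.12 to 0.06 in the controls. Trp53, which encodes p53, had 5269 ± 479 in controls and 5811 ± 401.1 in knockouts and did not pass the test (adjusted p = 0.481).

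Interferon-stimulated genes were among those that rose. Of 43 tested members, 17 rose and none fell over all genes tested, and 30 rose adjusted over the list alone. Ifi27l2a had the lowest adjusted p, with 61.3 ± 16.9 in controls and 368 ± 116 in knockouts (5.85-fold; adjusted p = 3.27e-05). Ifi27 rose from 1159 ± 76.8 to 2239 ± 495, Oasl1 from 132 ± 14.9 to 280 ± 29.1, Lgals3bp from 2795 ± 691 to 5328 ± 976 and Oas1a from 755 ± 97.2 to 1392 ± 310. The median fold of the list was 1.67 (camera adjusted p = 8.65e-28). That call was lost with an estimated correlation (adjusted p = 0.156 with an estimated correlation). Knockout 8 had the highest list score, 1.20, against 0.56 to 0.73 in the other knockouts and -0.15 to 0.24 in the controls. Without knockout 8, 17 members rose, with a median log2 fold change of 0.57; 8, 10, 9, 9 and 11 rose without control 2, control 3, control 4, knockout 5 and knockout 7, each left out alone. With no intensity trend 2 rose, and Ifi27 (adjusted p = 0.0503), Lgals3bp (0.110) and Oas1a (0.105) lost their calls; with the later neutrophil score as a covariate, chosen after seeing the data, 7 rose.

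The antigen presentation genes of MHC class I moved the same way. Of 14 tested members, 6 rose and none fell, and 13 rose adjusted over the list alone. H2-Q6 went from 1231 ± 357 to 3862 ± 1728, H2-Q4 from 1919 ± 284 to 3386 ± 668, and Tap1, a subunit of the peptide transporter, from 5182 ± 671 to 7977 ± 942. Nlrc5, the transactivator of these genes, went from 1014 ± 246 to 1864 ± 359, and H2-D1 from 31260 ± 2897 to 42490 ± 5547. The camera call (adjusted p = 1.29e-15) was lost with an estimated correlation (adjusted p = 0.238 with an estimated correlation). Knockout 8 again scored highest, 1.00 against 0.37 to 0.50 in the other knockouts. Reads can be shared between H2-Q and H2-D1 copies, and Tap1 overlaps Psmb9, so the split between these genes is uncertain. The call of H2-D1 was lost without control 2, 3 or 4 or knockout 5, 6 or 7 (adjusted p 0.0542 to 0.159). With no intensity trend 0 of the 14 rose (adjusted p 0.102 to 0.197 for the 5 genes named here), with the later neutrophil covariate 3 did, and with array weights 9 did.

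Among proliferation genes, no member of the S-phase list passed the test over all genes, and 1 of 35 fell adjusted over the list alone. Mcm6 had 24617 ± 925 in controls and 21918 ± 2010 in knockouts, and Mcm5 had 21572 ± 2142 and 18842 ± 840; 33 of the 35 log2 fold changes were below 0. The list as a whole was lower (median fold 0.893; camera adjusted p = 6.08e-08), a call lost with an estimated correlation (adjusted p = 0.320 with an estimated correlation). Its score was -0.22 to -0.15 in knockouts 5 to 7, but -0.03 in knockout 8, within the controls (-0.04 to 0.06). In the G2/M list 2 of 40 members rose and none fell, with 2 adjusted over the list alone. Gtse1, a microtubule-associated regulator of p53, went from 1470 ± 142 to 3162 ± 365 and Cdc25b, a phosphatase that activates cyclin-dependent kinases, from 754 ± 29.2 to 1265 ± 330. The G2/M list had a median fold of 1.04 (camera adjusted p = 0.00559; adjusted p = 0.574 with an estimated correlation); its scores in knockouts 6 (0.06) and 8 (-0.05) lay within the controls (-0.06 to 0.09). The G2/M list call was lost without control 1 (0.0942), knockout 5 (0.0899) or knockout 7 (0.0502) or with the immediate early covariate (0.180), and that of Cdc25b without any 1 library other than knockout 8 (adjusted p 0.0555 to 0.140) or with no intensity trend (0.203). Without knockout 8, 5 S-phase genes fell and 4 G2/M genes rose.

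In the list of senescence genes and cell cycle inhibitors 2 of 14 members rose, 5 adjusted over the list alone. The 2 were Cdkn1a, also a member of the p53 list, and Ccnd1, the cyclin D1 gene, which went from 489 ± 53.3 to 1663 ± 405 (list camera adjusted p = 1.18e-05, adjusted p = 0.156 with an estimated correlation). The list mixes cell cycle inhibitors with cyclin D genes, which are not inhibitors, so its upward call has no single reading. None of 25 MYC target genes passed the test, over all genes or adjusted over the list alone; Ncl had 42024 ± 8441 and 47350 ± 5180, and Npm1 had 22136 ± 1354 and 21541 ± 3170 (camera adjusted p = 0.00115, upward; adjusted p = 0.497 with an estimated correlation). None of 40 DNA repair genes passed either way; Topbp1 had 11438 ± 554 and 10932 ± 260, and H2afx had 9392 ± 536 and 10566 ± 1390 (camera adjusted p = 0.0188, downward; adjusted p = 0.480 with an estimated correlation). Ccnd1 overlaps LTO1 on the opposite strand (mean 456.7 normalised counts), so its level is uncertain. The MYC list call was lost without knockout 8 (0.114), and the DNA repair list call without control 1 (0.194), knockout 5 (0.0720) or knockout 8 (0.0973). The DNA repair list call was also lost at equal totals (0.0665), with quantile normalisation (0.113), with array weights (0.0976) and without control 1 and knockout 8 together (0.36).

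Some stem cell and multipotent progenitor genes rose. Of 22 tested members, 4 rose over all genes tested, and 10 rose and 1 fell adjusted over the list alone. Flt3, a cytokine receptor of early progenitors, went from 423 ± 126 to 880 ± 130 and Vwf, the von Willebrand factor gene, from 28.7 ± 4.2 to 77.4 ± 5.0. Ifitm3, which interferon also induces, went from 2063 ± 532 to 5007 ± 1096, and Txnip, a regulator of thioredoxin, from 2354 ± 412 to 3702 ± 262. The camera adjusted p was 1.29e-08 (adjusted p = 0.156 with an estimated correlation). In the list of leukaemia-associated genes Flt3 was the 1 of 18 members that rose, with 3 adjusted over the list alone (camera adjusted p = 0.00559; adjusted p = 0.320 with an estimated correlation). With the later neutrophil covariate that list lost its call (0.0607) and none of its members rose. The calls of Flt3 (adjusted p = 0.0503) and Vwf (0.05104) were lost without knockout 7, where 2 stem cell list genes rose. With no intensity trend 1 did, as Ifitm3 (0.0526), Txnip (0.102) and Flt3 (0.136) lost their calls.

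In the GMP and primary granule list Fcnb was the 1 of 28 members that fell, and it was also the 1 that fell adjusted over the list alone, while 25 had a log2 fold change below 0 (median fold 0.870; camera adjusted p = 2.07e-06; adjusted p = 0.320 with an estimated correlation). The granule score was -0.36 to -0.24 in knockouts 5 to 7, but -0.07 in knockout 8, within the controls (-0.20 to 0.12). Of 12 eosinophil genes 2 fell over all genes tested and 7 adjusted over the list alone. Ear1 went from 167 ± 25.9 to 33.9 ± 8.0 and Ear2 from 214 ± 51.9 to 52.2 ± 36.4. Both encode eosinophil-associated ribonucleases, similar in sequence, between which reads can be shared. The median fold of the eosinophil list was 0.492 (camera adjusted p = 1.97e-07; adjusted p = 0.320 with an estimated correlation). Its score was -1.94 to -0.87 in knockouts 5 to 7, but 0.07 in knockout 8 and -0.27 to 0.24 in controls. Without knockout 8, 9 of its members fell, and without any 1 control or knockout 5, 1 did. In the granule list 5 genes fell without control 1 and 5 without knockout 8, and neither list passed by fry (adjusted p = 0.120 for each). With no intensity trend 0 granule genes and 1 eosinophil gene fell, and with array weights 11 and 8 did.

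Markers of other cells that a marrow sort could hold moved unevenly. Of 13 mast cell and basophil genes 1 fell, Gzmb, and 2 adjusted over the list alone (camera adjusted p = 0.0145, adjusted p = 0.480 with an estimated correlation). Knockout 8 scored 0.24, the other knockouts -1.21 to -0.45 and the controls -0.39 to 0.17. Selp, which encodes P-selectin, rose from 150 ± 73.1 to 1001 ± 151 and with Vwf made 2 of 12 megakaryocyte genes that rose. Padi4, an arginine deiminase of neutrophils, rose from 325 ± 32.7 to 763 ± 79.8 and was the 1 of 19 later neutrophil genes to pass. Ccr2, a chemokine receptor, rose from 6988 ± 906 to 9737 ± 962 (1 of 23 monocyte and macrophage genes). Bst2 and Flt3 rose among 11 dendritic cell genes; Bst2, also interferon-stimulated, went from 2315 ± 233 to 3539 ± 551. The dendritic cell score was 0.88 in knockout 8, -0.63 to -0.33 in the other knockouts and -0.24 to 0.33 in the controls. Hbb-bs, a haemoglobin chain, rose from 8 to 170 reads (1 of 15 erythroid genes), and Vwf and Pecam1 rose among 5 stromal and endothelial genes. Gzmb was the 1 of 5 T and NK cell genes that fell, and none of 8 B cell genes passed. Adjusted over the list alone, 2 megakaryocyte, 2 dendritic cell and 3 erythroid genes rose, 5 later neutrophil genes rose and 5 fell, 2 monocyte and macrophage genes rose and 3 fell, 2 stromal and endothelial genes rose and 1 fell, 1 T and NK cell gene fell and no B cell gene passed. The camera adjusted p of these lists other than the mast cell and basophil list lay between 0.0726 (erythroid) and 0.858 (later neutrophil). Some passed under other settings: dendritic cell genes, 6 of them above 0 and 5 below, with a minimum mean of 50 (6.70e-04), edgeR (0.0123), DESeq2 (0.00665) and without knockout 6 (0.0420), and erythroid genes with no filter (0.0428), edgeR (0.0407), DESeq2 (0.0347) and without knockout 7 (0.0128). Stromal and endothelial genes passed with a minimum mean of 50 (0.0471), DESeq2 (0.0383) and without knockout 5 (0.0175), and B cell genes with no intensity trend (0.0432) and without knockout 6 (0.0324). With the later neutrophil covariate megakaryocyte (0.0130), erythroid (3.70e-04) and dendritic cell genes (0.0132) passed and the mast cell and basophil list had 0.861; with the immediate early covariate erythroid (0.0125) and dendritic cell genes (0.0145) passed and the mast cell and basophil list had 0.198. The calls were lost of Pecam1 without control 2, 3 or 4 or knockout 5, 6 or 7 (adjusted p 0.0568 to 0.151), Ccr2 without control 3 or 4 or knockout 5 or 7 (0.0617 to 0.0991) and Hbb-bs without knockout 6 or 7 (0.0669 and 0.0952), and of the mast cell and basophil list without control 2 (0.0534) or knockout 5 (0.2) or 7 (0.0670), with a minimum mean of 50 (0.115), edgeR (0.127) or DESeq2 (0.0941). With no intensity trend Ccr2, Bst2, Hbb-bs and Pecam1 lost their calls (0.103 to 0.193). Without knockout 8, 6 mast cell and basophil genes and 5 later neutrophil genes fell, and without control 1, 4 later neutrophil genes fell.

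**Figure D3:**
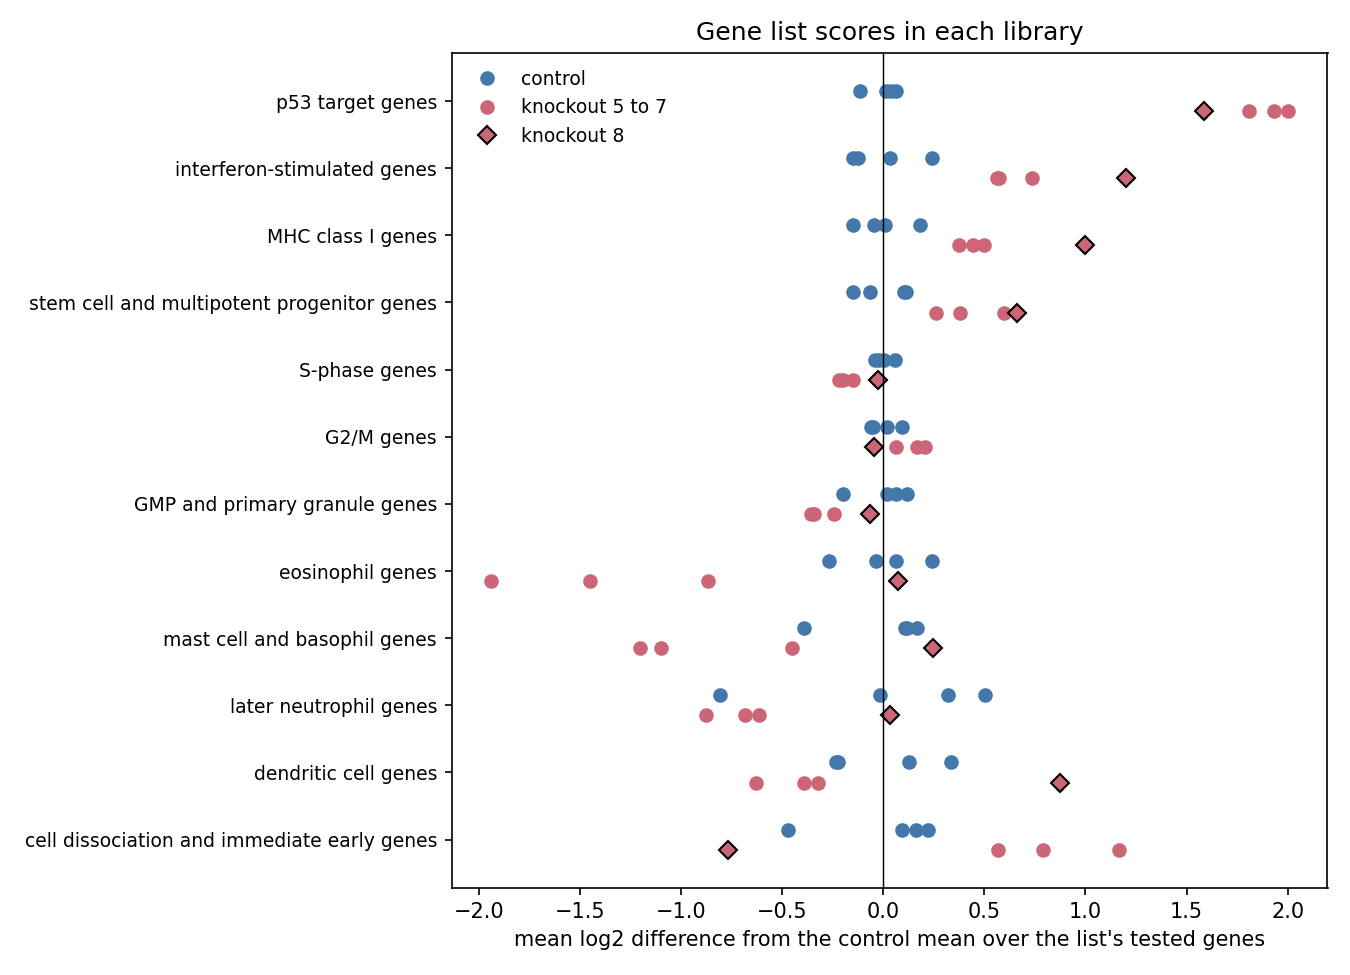
List score of each library, the mean log2 difference from the control mean over the list's tested genes (horizontal axis), for 12 of the 32 lists; circles are controls and knockouts 5 to 7, and diamonds are knockout 8. In the p53 list all 4 knockouts lie at 1.59 to 2.00, while in the eosinophil list knockout 8 lies at 0.07 and the other knockouts at -1.94 to -0.87.

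Stress and signalling lists gave few calls. Icam1, an adhesion molecule induced by NF-kB, rose from 624 ± 90.2 to 1103 ± 110 and was the 1 of 17 NF-kB and inflammatory genes to rise, also adjusted over the list alone (camera adjusted p = 0.00559; adjusted p = 0.480 with an estimated correlation). None of 19 dissociation and immediate early genes passed over all genes tested and 1 did adjusted over the list alone; Hsp90aa1 had 21177 ± 3156 and 19330 ± 2348, and Fos had 16341 ± 5125 and 17771 ± 9275 (camera adjusted p = 0.0113, upward; adjusted p = 0.537 with an estimated correlation). That list scored 0.57 to 1.17 in knockouts 5 to 7 and -0.77 in knockout 8, and the NF-kB list 0.54 to 0.63 and -0.36. None of 13 mitochondrial transcripts passed, over all genes or adjusted over the list alone; mt-Co1 had 106195 ± 29782 and 116331 ± 22109, and mt-Cytb had 41349 ± 10742 and 45993 ± 10117 (camera adjusted p = 0.0433, upward; adjusted p = 0.599 with an estimated correlation). Sesn2 and Ddit4, both induced by stress, rose from 298 ± 37.2 to 1190 ± 342 and from 205 ± 52.3 to 420 ± 85.9, 2 of 23 genes of the unfolded protein and integrated stress response list, in which 2 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.796). Sesn2 is also a member of the p53 list. The cholesterol synthesis list did not pass (camera adjusted p = 0.248). The lists of nucleic acid sensors, RNA-DNA hybrid processing, apoptosis, ribosomal proteins, glycolysis and sex-linked genes held no gene past the test over all genes and had camera adjusted p of 0.807, 0.513, 0.374, 0.810, 0.127 and 0.127; adjusted over the list alone 1 nucleic acid sensor gene rose and no gene of the others passed. List calls were lost for NF-kB without knockout 5 (0.0529) or 7 (0.0502), for immediate early genes without control 3 (0.184) or knockout 5 (0.0848) or 6 (0.382), and for mitochondrial transcripts without control 1 (0.381), 2 (0.148) or 4 (0.159) or knockout 5 (0.481) or 7 (0.0726). The mitochondrial call was also lost at equal totals (0.0611), with no intensity trend (0.102), with edgeR (0.0643), DESeq2 (0.183), protein-coding genes alone (0.0738), the immediate early (0.1005) or later neutrophil covariate (0.335), and without control 1 and knockout 8 together (0.0546). Glycolysis genes were called higher with quantile normalisation (0.0315) and without control 1 (0.0336) or knockout 5 (0.0357), and ribosomal protein genes without control 3 (0.0460). The sex-linked list was called lower without control 1 and knockout 8 together (0.0380), and ribosomal protein genes were too (0.0461). With the immediate early score as a covariate the NF-kB list lost its call (0.349) and its median log2 fold change went from 0.31 to 0.09, and with the later neutrophil score it had 0.235 and the immediate early list 0.864; both covariates were chosen after seeing the data. The call of Ddit4 was lost without knockout 5 (0.0568) or 6 (0.0592) or with no intensity trend (0.121), while without knockout 8, 5 NF-kB and 4 immediate early genes rose.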

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

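The tests of the interferon, eosinophil and Rnaseh2b patterns in this part were all chosen after the results were seen; the count over other splits of the libraries was planned. Of 210 sets of 4 values examined (69 genes, 32 list scores and 4 library measures in 2 groups), 20 had 1 library far from the other 3, where chance gives about 1 in 20.

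Knockout 8 stood apart for Nrg1 (415.8, the other knockouts 277 to 285.2), St8sia6 (112.6, others 51.6 to 60.3), Oasl1 (323.4, others 262.9 to 270.1), Lgals3bp (6778, others 4712 to 5027), H2-Q6 (6445, others 2821 to 3162), Tap1 (9387, others 7450 to 7587) and Nlrc5 (2402, others 1654 to 1709), and for the NF-kB score (-0.36, others 0.54 to 0.63). Control 1 did so for Zmat3 (119.9, others 48.2 to 51.0), Topbp1 (12262, others 11070 to 11253) and the mast cell and basophil score (-0.39, others 0.11 to 0.17). In Eda2r and Tnfsf4 control 1 had 4.7 normalised counts each and the other controls 0. Control 3 did so for Pmaip1 (211.1, others 259.4 to 268.1), mt-Co1 (150410, others 85950 to 96304), mt-Cytb (57418, others 34889 to 36755), the mitochondrial score (0.51, others -0.24 to -0.12) and the mitochondrial share of values (1.03%, others 0.605 to 0.651%). Control 2 did so for Acp1 (1560, others 1354 to 1384) and the stromal and endothelial score (0.13, others -0.06 to -0.04).

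Of the 35 splits of the 8 libraries into 4 and 4, 2 gave at least as many genes as the real 234, the real one included, so by the count alone chance is not excluded. The other one set control 1 with knockouts 5 to 7 against the rest and gave 442 genes, more than the real split. That points to a structure of the samples that crosses the groups. By the sample numbers in the labels, it is the first 4 libraries against the last 4. Knockouts make up 3 of the first 4 and 1 of the last 4, so genotype and sample order are partly confounded. What the sample numbers follow is not given in the sources used here. Those 442 shared 8 genes with the 234, where independent lists would share 6.2. The 2 splits differ only in the places of control 1 and knockout 8, so their lists are not independent. The overlap therefore cannot tell whether genotype and this structure act on separate genes. The 442 held 1 p53 target gene, 0 interferon-stimulated genes, 6 later neutrophil genes and 4 eosinophil genes. As lists, p53 target genes (camera adjusted p = 1.37e-08) and interferon-stimulated genes (0.00400) were higher in that split too, which keeps 3 of the 4 knockouts together. It called some lists with a lower adjusted p than the real split: GMP and primary granule genes (1.07e-10 against 2.07e-06), immediate early genes (3.92e-10 against 0.0113), eosinophil genes (1.03e-08 against 1.97e-07), NF-kB genes (4.53e-06 against 0.00559) mast cell and basophil genes (1.03e-05 against 0.0145), later neutrophil genes (2.76e-05 against 0.858), ribosomal protein genes (1.67e-04 against 0.810) and sex-linked genes (0.0340 against 0.127). The next highest split gave 2 genes.

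Some interferon-stimulated genes rose in the knockouts. The tables argue against knockout 8 as the whole cause, since without it the list's median log2 fold change was 0.57, against 0.74 with all libraries, and fry still called the list (adjusted p = 0.0140), although camera did not with an estimated correlation (adjusted p = 0.183 with an estimated correlation). Handling as read from immediate early genes stays open for knockouts 5 to 7. With that score as a covariate the median was 1.03, while 1502 genes moved by over 0.2. The covariate cannot decide for these libraries, since both scores were raised there (immediate early 0.57 to 1.17, controls -0.47 to 0.22). Its slope rested largely on knockout 8, which had the lowest immediate early score (-0.77) and the highest interferon score (1.20). For knockouts 5 to 7 the tables argue against dendritic cells rich in class II transcripts, which a lineage-negative sort could leave in part. Cd74, H2-Aa, H2-Ab1 and H2-Eb1 together had at most 675.5 normalised counts, against 518.9 to 795.8 in controls. The interferon list summed to at least 15309.9 above the control mean, though control 1 itself stood 8673.1 above it. Dendritic cells low in class II transcripts are not covered and stay open. Bst2 and Flt3 of the dendritic cell list were above every control in these knockouts, while the list score was -0.63 to -0.33, against -0.24 to 0.33 in controls. For knockout 8 dendritic cells stay open for part of the rise (1432.1 for the 4 class II genes, with Cd74 at 100.1 and H2-Aa at 159.8). The excess of these 4 genes over the lowest control was 2.87% of the rise of the summed interferon list in knockout 8. In knockouts 5 to 7 it was 0.136% to 1.02%. Of the dendritic cell list 1 member, Bst2, is shared with the interferon list. An effect of the genotype stays open for all 4 knockouts as a hypothesis. Sample order stays open for knockouts 5 to 7. Without knockout 8 all knockouts come before all controls in the sample numbers, so that fit cannot separate order from genotype. The split of the first against the last libraries, which keeps knockouts 5 to 7 together, also called the list higher (camera adjusted p = 0.00400). Knockout 8, the last library, nevertheless had the highest score (1.20).

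The eosinophil list score was below that of each control in knockouts 5 to 7 and not in knockout 8. For knockouts 5 to 7 the tables argue against reads shared between Ear copies: without knockout 8, 6 of the 9 members outside that family fell over all genes tested, with a median log2 fold change of -0.84 (median SE 0.214; -0.40 with all knockouts), and the summed count of the 5 Ear genes listed was 69 to 210.3, against 528.2 to 1207.1 in controls. In knockout 8, where that sum was 539.8, the split between copies stays open. Less mature granulocytes in the sort stay open: with the later neutrophil score as a covariate the median went from -1.02 to -0.51 (median SE 0.351 and 0.341) and the list stayed past the threshold (camera adjusted p = 0.00267). This partial loss decides neither way, because the score partly goes with the groups. It was -0.87 to -0.62 in knockouts 5 to 7 and 0.035 in knockout 8, against -0.81 in control 1 and -0.015 to 0.504 in the other controls. Sample order stays open as well. By the sample numbers in the labels, knockouts 5 to 7 come first and knockout 8 last. The split of the first against the last libraries called the eosinophil list with a lower camera adjusted p (1.03e-08) than the real split (1.97e-07). Control 1, among the first libraries, had the lowest control score (-0.27), above knockouts 5 to 7 (-1.94 to -0.87). Without the covariate the list was not past the threshold with an estimated correlation (adjusted p = 0.320 with an estimated correlation, and 0.183 without knockout 8), and an effect of the genotype on this lineage was not tested.

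Rnaseh2b in controls 3 and 4 was below that in controls 1 and 2. RNA of knockout cells would have to make up 39.2% and 41.9% of controls 3 and 4, judged against the other controls, yet over the 99 genes at least 2-fold higher in knockouts the upper quartile of that share was 3.83% and 2.51%. The tables also argue against an altered dose of the whole region: the 23 tested genes within 2 Mb had medians of 0.10 and 0.05 on the log2 scale relative to the control mean, while Rnaseh2b had -0.45 and -0.50. Whether 1 allele of Rnaseh2b alone differs in these mice is open, since gene totals cannot show it.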

How the results depend on the processing

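Alternatives with a covariate, with control 1 and knockout 8 left out together, with protein-coding genes alone or with the estimated correlation without knockout 8 were chosen after seeing the data. Rnaseh2b and the p53 list kept their direction and call under each alternative run. The 234 genes changed in knockout GMP became 104 without the trend, 1001 with array weights (547 higher, 454 lower), 558 with DESeq2, 110 at 2-fold or more, 130 with the later neutrophil covariate and 1440 without control 1 and knockout 8, and 135 to 569 over the omissions of 1 library; the cause was not tested, except that the 2-fold limit leaves fewer genes by construction. Of the 16 lists, 1 stayed past the threshold with an estimated correlation, with all libraries and without knockout 8. The interferon-stimulated genes then had adjusted p = 0.156 and 0.183, S-phase genes 0.320 and 0.183, and G2/M genes 0.574 and 0.454. G2/M genes had 0.180 with the immediate early covariate and 1.03e-05 to 0.0942 over the omissions. Of 52 named genes past the threshold, 23 lost it without the trend and 13 with the later neutrophil covariate. No paired analysis was possible because the groups share no replicate numbers. An Xist covariate was not run, since the libraries showed Y-linked genes throughout.

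Values that turned direction were mostly not past the threshold. The later neutrophil genes had adjusted p = 0.411 with no filter, 0.827 at equal totals, 0.357 with array weights, 0.920 with edgeR, 0.836 with the estimated correlation without knockout 8, 0.00883 without control 1 and knockout 8 together, and 0.202 to 0.877 over the omissions. Ribosomal protein genes had 0.445 with array weights, 0.873 with the estimated correlation without knockout 8, 0.0461 without both libraries and 0.0460 to 0.904 over the omissions. The unfolded protein and integrated stress response list had 0.690 with quantile normalisation, 0.941 with array weights, 0.712 with DESeq2, 0.836 with the estimated correlation without knockout 8, 0.320 without both and 0.382 to 0.995. Erythroid genes had 0.928 with the estimated correlation without knockout 8, 0.870 without both and 0.0128 to 0.889, and megakaryocyte genes 0.786 without both. RNA-DNA hybrid and ribonucleotide processing had 0.966 with quantile normalisation and 0.115 to 0.963. Nucleic acid sensors and metabolism had 0.894 and monocyte and macrophage genes 0.448 with the later neutrophil covariate, and 0.419 to 0.995 and 0.261 to 0.9994 over the omissions. The cell dissociation and immediate early genes had 0.177 with their own covariate. Log2 fold changes that crossed 0 were those of Rnaseh2c (-0.042 with array weights, -0.064 without both, -0.051 to 0.048), Ddx3y (0.004 at equal totals, 0.019 and 0.068 with the covariates, -0.095 to 0.016), Uty (0.017 with the later neutrophil covariate, -0.174 to 0.022), Npm1 (0.048 and 0.011 with the covariates, -0.146 to 0.003) and Fos (-0.471 and -0.361 with the covariates, -0.294 to 0.405). Fos is itself a member of the immediate early list, so its value with that covariate (-0.471) was adjusted in part for itself. The cause of the other turns was not tested. Depth limits the folds of genes with few control reads, such as Zfp365.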

Other observations

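Some mast cell and basophil genes of knockout 8 add to what sets that library apart. Its eosinophil score lay above the other knockouts but within the controls. The genes in this part were chosen after their values were seen. As lists, its mast cell and basophil score was 0.24 (controls -0.39 to 0.17) and its eosinophil score 0.07 (controls -0.27 to 0.24). Gzmb of the mast cell and basophil list went the other way, with 11.5 normalised counts in knockout 8, the lowest of all libraries. Fcer1a, the high-affinity IgE receptor alpha chain, stood at 2524 normalised counts in knockout 8, against 246 to 490 in the other knockouts and 245 to 463 in the controls. Mcpt8, a basophil protease, stood at 3212.5 against 1227 to 1578 in the other knockouts and 1682 to 2507 in the controls, and Gata1, a transcription factor of several of these lineages, at 291.6 against 62.1 to 82.8 and 121.2 to 151.1. Prg2, an eosinophil granule protein, stood at 16428 in knockout 8, within the control range of 12803 to 23089, and at 3372 to 6454 in the other knockouts. Ear1 and Ear2 of knockout 8 stood at 45.2 and 93.4, below every control (at least 144.2 and 170.5). The erythroid list, which also holds Gata1, scored 1.185 in knockout 8, against 0.25 to 0.58 in the other knockouts and -0.42 to 0.24 in the controls.

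S100a8, a calcium-binding protein of maturing neutrophils, had 501 normalised counts in control 1 and 2465 to 5218 in the other controls, and 165 to 452 in knockouts 5 to 7 and 1058 in knockout 8. The difference between the groups did not pass the test (limma adjusted p = 0.0745; n = 4 per group). The later neutrophil score of control 1 was -0.81, next to -0.87 to -0.62 in knockouts 5 to 7, while its p53 score was 0.04.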
